A study of Oryza sativa Indica Group with 6 samples.

How the data were processed

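Total RNA from seedlings of 3 T-DNA insertional mutant lines of rice, OsPE, Osoc and Ossl, was labelled with biotin and hybridized to the Affymetrix Rice Genome array. Each line had 2 arrays, which the labels call biological replications, and the seedlings were collected 15 days after germination. No untransformed line is among the samples, so each line was compared with the other two. The meaning of the line names, the sites of the insertions and any growth or labelling batch are not given in the sources used here.

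The deposited values are 1 signal intensity per probe set and array on a linear scale. Per the labels the authors used GCOS 1.2, the Affymetrix operating software; the algorithm behind the signals is not given in the sources used here. On every array the mean without the lowest and highest 2% of the probe sets was 500.1, so the arrays had been scaled to a common mean. The median signal per array lay between 37.4 and 42.8, and the median log2 values spanned 0.142, so this scaling was kept. Arrays carry no counts, and it is the number of arrays that limits the precision.

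The 123 control probe sets of the manufacturer were left out of the tests, and 57258 others remained. A probe set was tested when its signal exceeded the 40th percentile of its array on at least 2 of the 6 arrays, which held for 39629. Differences were computed on log2(signal + 16), so the folds given are ratios of signal + 16 and understate changes at low signals. The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with the variance as a trend of the mean signal), with all 6 arrays in 1 fit. Its moderated tests were two-sided, and Benjamini-Hochberg adjusted p below 0.05 was the threshold. The fit had 3 residual degrees of freedom, to which the prior added 8.98. A probe set was said to set a line apart when both comparisons with that line passed in the same direction.

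Gene symbols came from the probe-to-gene table and from the names of the reference annotation (assembly ASM3414082v1, Oryza sativa Japonica Group). The series text names Basmati and the organism label Oryza sativa Indica Group; differences in probe sequence between cultivars could not be checked. Of the probe sets, 22436 matched 1 gene symbol, 95 matched several and 34850 matched none. The matched ones stand for 17905 genes, of which 2457 carry a name other than a locus number. Genes known by a locus number only could not enter the lists or the named genes.

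For 32 themes, gene lists were tested with camera (limma, preset correlation of 0.01), each against the other genes tested. The p-values were adjusted over 27 lists in 3 comparisons, since 2 themes matched no gene and the others held fewer than 5 genes. A gene was represented by its probe set with the highest mean. The themes were fixed before the data were examined, as were the tests, the thresholds and the rule for named genes. Most description patterns matched no symbol, because the tables hold symbols and aliases only. Symbol patterns for the same themes were therefore added when the tables were seen, before any line was compared, and symbols that matched by their letters alone were removed.

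The rule took, per comparison and direction, the 10 named genes with the largest change among those past the threshold whose arrays of one line all lay above those of the other. It also took the 5 genes per direction that set each line apart most, and up to 4 members of each list with the lowest adjusted p in the comparison where the list's own p was lowest. All reporter probe sets were read by their IDs, since the lines carry insertions.

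The procedure was tested on simulated data with 39280 probe sets, among them changed sets drawn from all signal levels. For Ossl against OsPE, 28% of the changed probe sets were recovered at 1.5-fold, 30% at 2-fold, 48% at 4-fold and 70% at 8-fold. For Ossl against Osoc the shares were 24%, 28%, 48% and 72%. In either comparison 7 of 39073 unchanged probe sets were called. A shift of 0.5 (log2) of the 15 chlorophyll biosynthesis genes was recovered by the list test in 2 of 2 comparisons, and 2 of 79 other list tests were called. The noise was drawn from the fitted variance trend, independently for each probe set and array. The recovered shares and the 7 calls therefore take that trend as given and do not test it. As the noise was independent, the list counts do not cover genes that vary together.

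The alternatives tried were other offsets on the log scale, quantile normalization, median centring, no filter or a stricter one, variance models without the trend or with robust weights, and the replicate number as a block. Further ones were stricter thresholds, only the arrays of the lines compared, each array left out in turn, and for the lists an estimated correlation, fry, and the mean of a gene's probe sets. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.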

Results

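Signals of 57258 probe sets were read in 15-day-old seedlings of the rice insertion lines OsPE, Osoc and Ossl, with 2 arrays per line. The comparisons ask how transcription differs between these lines, and an untransformed line was not used here. Values are mean signals with their SD (n = 2), and folds are on the offset scale. Across probe sets, which are not independent replicates, log2 signals of arrays of 1 line correlated at 0.972 to 0.976, and those of different lines at 0.962 to 0.969. The first principal component held 29% of the variance and set the Ossl arrays apart, the second held 23.1% and separated OsPE from Osoc, and the third held 17% and separated the Ossl arrays from each other. Over the 3 lines, 5849 of 39629 probe sets (14.8%) differed by limma's moderated F test. That number was 431 when the variance was not modelled as a trend of the signal and 3740 without Osoc replicate 2.

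In Osoc compared with OsPE, the lectin gene ML, also named salT, rose 7.19-fold, from 87.7 ± 12.7 to 727 ± 2.5 (adjusted p = 5.12e-07), and Pir7b rose 6.58-fold, from 222 ± 43.7 to 1538 ± 25.8 (adjusted p = 1.92e-07). DCL2A, a Dicer-like enzyme of small RNA production, rose 4-fold, from 1016 ± 42.4 to 4107 ± 67 (adjusted p = 4.28e-08), and its dimmer probe set did not pass (adjusted p = 0.094). The small heat shock protein gene HSP18.1 rose 2.98-fold on 1 probe set and by 1.15 (log2) on the other, the late embryogenesis abundant protein gene LEA19 rose 2.91-fold and the chitinase gene Cht2 2.9-fold. Their lists did not pass: of 41 heat shock genes 2 rose and 6 fell, with 4 and 7 when adjusted over the list alone (camera adjusted p = 0.826). Of 27 genes of abscisic acid and late embryogenesis abundant proteins 2 rose and 8 fell, with 3 and 12 over the list alone (0.0746), and of 20 genes of pathogenesis-related proteins and chitinases 3 rose and 4 fell, as over the list alone (0.847). BURP16, which encodes a BURP domain protein, fell 4.72-fold, from 1235 ± 19.7 to 249 ± 3.2 (adjusted p = 1.32e-08). ITPK1, an inositol phosphate kinase gene, fell 2.85-fold, from 4441 ± 153 to 1546 ± 16.5 (adjusted p = 1.92e-07). The jasmonate repressor gene JAZ10 and CESA7, a cellulose synthase of secondary walls, fell 2.85-fold and 2.4-fold, while the brightest probe set of JAZ10 fell 1.75-fold, from 9735 ± 1.8 to 5543 ± 134. The germin-like gene GER2 passed as well (adjusted p = 0.000195), from 9.1 ± 4.5 in OsPE, which is below the 40th percentile of those arrays, to 182 ± 27.6, so its fold is not reliable.

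Probe sets of the same gene did not always move together. ARD1 fell 8.14-fold on 1 probe set (adjusted p = 6.37e-05), while its other probe set differed by 0.15 on the log2 scale (adjusted p = 0.705). AARE1 fell 8.13-fold on 1 probe set (adjusted p = 4.44e-06), while its other 2 probe sets rose by 1.07 and 1.06 on the log2 scale (adjusted p = 0.00141 and 4.44e-06). No direction is therefore given for AARE1 as a gene.

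Of 25 cytosolic ribosomal protein genes 19 rose in Osoc against OsPE, 0 fell and 6 did not pass, with 24 rising when adjusted over the list alone. RPL11 rose 1.55-fold, from 6744 ± 117 to 10448 ± 162, and RPL30 rose 1.56-fold. The list passed with camera at adjusted p = 2.42e-20, and had adjusted p = 0.204 with an estimated correlation. Of 15 chlorophyll biosynthesis genes 7 rose, 0 fell and 8 did not pass, with 10 rising when adjusted over the list alone. PORA, a protochlorophyllide reductase, rose from 912 ± 68.5 to 2058 ± 22.1, and GSA, of the early steps, from 6870 ± 56.9 to 10184 ± 30.7. The list had camera adjusted p = 1.56e-08, and adjusted p = 0.204 with an estimated correlation. Of 6 glutathione S-transferase genes 2 rose, GSTU6 and GST1, and 4 did not pass, with 3 rising when adjusted over the list alone (camera adjusted p = 0.0051; adjusted p = 0.314 with an estimated correlation).

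Lists with lower signals and a call in Osoc against OsPE concerned jasmonate, cell walls, WRKY factors and cytokinin. Of 37 jasmonate genes 13 fell, 0 rose and 24 did not pass, against 14 that fell and 1 that rose when adjusted over the list alone. Besides JAZ10, the repressor genes JAZ7 and JAZ6 fell 1.45-fold each and JAZ11 fell 1.44-fold. The jasmonate list had camera adjusted p = 0.000534, and adjusted p = 0.204 with an estimated correlation. Of 48 genes of expansins and wall-modifying enzymes 11 fell, 0 rose and 37 did not pass, against 15 that fell and 1 that rose when adjusted over the list alone (camera adjusted p = 0.000788; adjusted p = 0.204 with an estimated correlation). Of 6 WRKY genes 3 fell, which were OsWRKY62 at 2.14-fold, OsWRKY76 at 1.59-fold and OsWRKY71 at 1.41-fold, and the same number fell when adjusted over the list alone. The WRKY list had camera adjusted p = 0.00906, and adjusted p = 0.396 with an estimated correlation. Of 28 cytokinin genes 6 fell, 0 rose and 22 did not pass, with 9 falling when adjusted over the list alone (camera adjusted p = 0.0278; adjusted p = 0.396 with an estimated correlation). The cytokinin call ended without OsPE replicate 1 (adjusted p = 0.0673) and without Osoc replicate 2 (adjusted p = 0.0805).

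In all, 2955 probe sets (7.5%) differed between Osoc and OsPE, 1430 higher and 1525 lower in Osoc, and 180 and 237 of these differed at least 2-fold. Without the variance trend 28 passed, and among the named genes only ML, Pir7b, DCL2A and BURP16 did so. The number was 1203 without OsPE replicate 1, 1201 without OsPE replicate 2, 1526 without Osoc replicate 1 and 1345 without Osoc replicate 2.

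**Figure D1:**
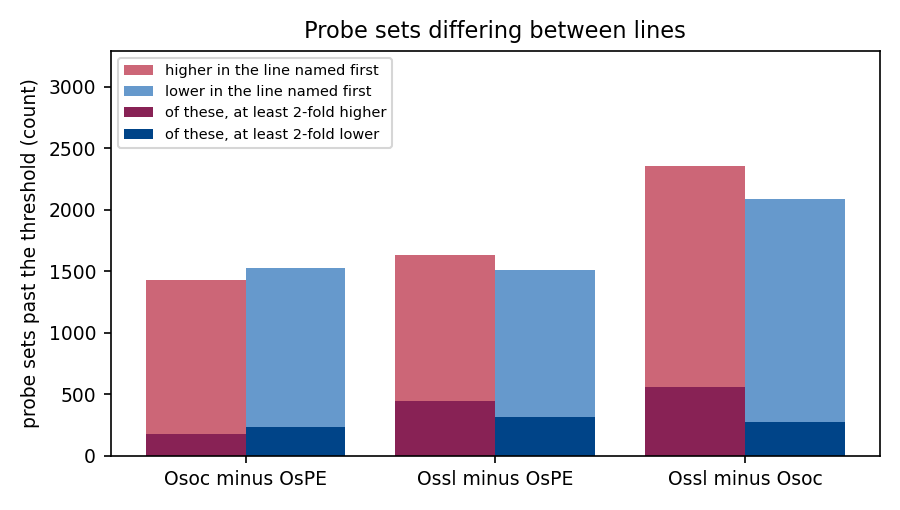
Number of probe sets past the threshold (vertical axis, count) in each comparison of lines, with bars for those higher and lower in the line named first and darker bars for those changed at least 2-fold. With all 6 arrays Ossl against Osoc had the most, with 2351 higher and 2090 lower.

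In Ossl compared with OsPE, JAZ2 and OsVIT1.2 showed the largest decreases among the named genes. JAZ2, a jasmonate repressor gene, read 3748 ± 148 in OsPE and 1.5 ± 0.9 in Ossl (adjusted p = 3.27e-12). The latter is below the 40th percentile of the Ossl arrays, which was 25.1 and 24.4, so no fold is given. OsVIT1.2, a vacuolar iron transporter gene, fell 13.32-fold, from 6382 ± 159 to 464 ± 21.5 (adjusted p = 3.27e-11). BURP16 rose 9.45-fold, from 1235 ± 19.7 to 11798 ± 394 (adjusted p = 1.58e-10), and Cht2 rose 7.41-fold, from 344 ± 2.1 to 2656 ± 163 (adjusted p = 3.11e-09). CYP71P1, listed also as a tryptamine hydroxylase (T5H), rose 5.84-fold, and ITPK1 fell 2.73-fold. JAZ10 fell 2.6-fold on 1 probe set and 1.94-fold on its brightest. Other genes split by probe set. The phosphatase gene OsPP2C45 rose 5.55-fold on 1 probe set, from 82.4 ± 18.8 to 526 ± 13.4, while its brighter one differed by -0.01 (log2; adjusted p = 0.958). QM1 fell 3.95-fold on 1 probe set, from 6064 ± 182 to 1524 ± 116, while of its other 3 the brightest differed by 0.17 (adjusted p = 0.0719), the next rose by 0.23 (adjusted p = 0.0403) and the dimmest did not pass, so no direction is given for QM1 as a gene. ARD1 fell 10.93-fold on 1 probe set and differed by 0.06 on the other (log2; adjusted p = 0.888).

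Of 13 measured genes of diterpenoid phytoalexin synthesis, the antimicrobial diterpenes of rice, 7 rose in Ossl against OsPE, 0 fell and 6 did not pass, also when adjusted over the list alone, and the median fold was 2.03. CYP71Z7 rose 5.75-fold, from 81.5 ± 14.8 to 547 ± 118, and CYP701A8 2.31-fold, from 460 ± 20.6 to 1083 ± 6.2. CYP99A2 read 41.3 ± 31.8 in OsPE and 486 ± 63.9 in Ossl (adjusted p = 0.000106). The diterpene cyclase gene CPS4 read 22.3 ± 5.4 and 186 ± 3.3 (adjusted p = 0.00258), and OsMAS, which acts in momilactone synthesis, 19.8 ± 21.6 and 186 ± 25.5 (adjusted p = 0.00302). These OsPE signals of CPS4 and OsMAS lie near the arrays' 40th percentile, so their folds are not reliable. The list had camera adjusted p = 0.000788, and adjusted p = 0.209 with an estimated correlation.

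Of 20 genes of pathogenesis-related proteins and chitinases 4 rose in Ossl against OsPE, 0 fell and 16 did not pass, with 7 rising when adjusted over the list alone. Those that rose were Cht2, the chitinase gene CH16 at 3.92-fold, GER2 and PBZ1, which rose from 7462 ± 377 to 12854 ± 113. The list had camera adjusted p = 0.0104, and adjusted p = 0.428 with an estimated correlation. Of 6 glutathione S-transferase genes 3 rose, with 4 rising when adjusted over the list alone. GST1 rose 3.02-fold, GSTU6 2.45-fold and GST-II 1.32-fold. That list had camera adjusted p = 0.00043, and adjusted p = 0.209 with an estimated correlation. Of 25 cytosolic ribosomal protein genes 16 rose, 0 fell and 9 did not pass, with 22 rising when adjusted over the list alone (camera adjusted p = 5.78e-11; adjusted p = 0.204 with an estimated correlation). Beside these groups, the poly-A control RNAs added to the samples, which measure handling and not the plants, were lower on the Ossl arrays, by -1.19 at the 5' end and -0.54 at the 3' end (mean log2 against the other lines).

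In all, 3138 probe sets (7.9%) differed between Ossl and OsPE, 1629 higher and 1509 lower in Ossl, and 443 and 318 of these differed at least 2-fold. Without the variance trend 382 passed, among them those of JAZ2, OsVIT1.2, BURP16, Cht2, CYP71P1 and CYP71Z7, and not those of CYP99A2, ARD1 or JAZ10. The number was 1495 without OsPE replicate 1 and 1520 without OsPE replicate 2.

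**Figure D2:**
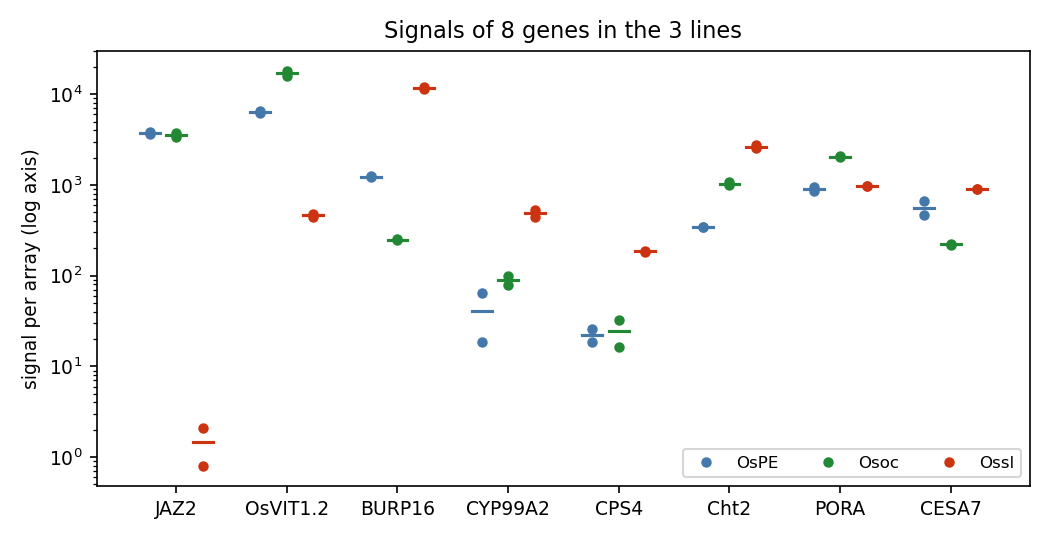
Signal per array (vertical log axis) of 8 genes in OsPE, Osoc and Ossl, with a point for each of 2 arrays and a line at their mean. JAZ2 sits at 3748 and 3576 in OsPE and Osoc and at 1.5 in Ossl, near the floor, while BURP16 is highest in Ossl at 11798.

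In Ossl compared with Osoc, BURP16, OsVIT1.2 and CAD6 differed with OsPE in between. For other genes 1 of the lines did not pass against OsPE, such as Osoc for JAZ2 and Ossl for NAS3. BURP16 was 44.58-fold higher in Ossl, at 11798 ± 394 against 249 ± 3.2, and OsVIT1.2 was 35.62-fold lower, at 464 ± 21.5 against 17128 ± 1637 (adjusted p = 1.21e-12 each). JAZ2 read 1.5 ± 0.9 against 3576 ± 215 (adjusted p = 1.21e-12). The lipoxygenase genes CM-LOX2 and CM-LOX1 rose 6.21-fold and 4-fold. CAD6 rose 5.25-fold, from 64.2 ± 1.3 to 405 ± 20.4, 4CL5 4.37-fold and PAL06 4.02-fold on 1 probe set and by 1.29 (log2) on the other. DCL2A fell 4.81-fold, from 4107 ± 67 to 841 ± 29 (adjusted p = 4.97e-09), and its dimmer probe set did not pass (adjusted p = 0.0669). The kinase gene CIPK10 fell 3.58-fold on its dimmest probe set and by 0.75, 0.3 and 0.28 (log2) on the others. QM1 fell 4.4-fold on 1 probe set, while its brightest differed by 0.07 (log2; adjusted p = 0.471). OsZIP3, of the zinc transporter family, fell 3.04-fold, from 517 ± 19.2 to 159 ± 12.2, and the nicotianamine synthase gene NAS3 fell 3.16-fold, from 1357 ± 47.7 to 420 ± 43.7, while osysl12 rose 1.59-fold (adjusted p = 0.000151). Of 31 iron homeostasis genes, OsVIT1.2, NAS3 and osysl12 among them, 4 rose, 6 fell and 21 did not pass, and 7 rose and 7 fell when adjusted over the list alone (camera adjusted p = 0.122). Of 22 phenylpropanoid and lignin genes 7 rose, 0 fell and 15 did not pass, and 8 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.122). The sugar transporter gene OsSWEET15 read 192 ± 3.1 in Osoc and 3.5 ± 2.2 in Ossl (adjusted p = 0.000277), the latter near the floor. AARE1 again split by probe set, with 1 of them 15.05-fold higher and another 5.45-fold lower in Ossl.

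Of 15 chlorophyll biosynthesis genes 11 fell in Ossl against Osoc, 0 rose and 4 did not pass, with 14 falling when adjusted over the list alone. PORA fell 2.1-fold, from 2058 ± 22.1 to 973 ± 13.6 (adjusted p = 8.36e-06), GluTR 1.58-fold, UPD2 1.53-fold and GSA 1.52-fold. The list had camera adjusted p = 4.26e-10, and adjusted p = 0.204 with an estimated correlation. Of 25 cytosolic ribosomal protein genes 8 fell, 0 rose and 17 did not pass, with 9 falling when adjusted over the list alone (camera adjusted p = 0.000507; adjusted p = 0.396 with an estimated correlation).

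In Ossl against Osoc, of 48 genes of expansins and wall-modifying enzymes 14 rose, 0 fell and 34 did not pass, with 15 rising when adjusted over the list alone. The cellulose synthase genes CESA7 and CESA4 rose 3.89-fold and 2.68-fold (0.95 on the log2 scale on the other probe set of CESA4), and the expansin genes EXPB4 and EXPB3 2.18-fold and 1.55-fold. The list had camera adjusted p = 0.000286, and adjusted p = 0.204 with an estimated correlation. Of 27 genes of abscisic acid and late embryogenesis abundant proteins 12 rose, 0 fell and 15 did not pass, with 14 rising when adjusted over the list alone. The dehydrin gene Dhn1 rose 1.62-fold, the phosphatase gene OsPP2C30 1.53-fold, and the kinase genes OsSAPK7 and OsSAPK3 1.74-fold and 1.46-fold. That list had camera adjusted p = 0.000373, and adjusted p = 0.204 with an estimated correlation.

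In Ossl against Osoc, of 13 diterpenoid genes 5 rose, among them CPS4, CYP99A2 and CYP701A8, 0 fell and 8 did not pass, with 7 rising when adjusted over the list alone (camera adjusted p = 0.00114; adjusted p = 0.209 with an estimated correlation). Of 20 genes of pathogenesis-related proteins and chitinases 6 rose, 0 fell and 14 did not pass, with 8 rising when adjusted over the list alone. Cht2 rose 2.79-fold on its brightest probe set, CH16 2.23-fold, GER7 1.87-fold and PBZ1 1.58-fold. The list had camera adjusted p = 0.00197, and adjusted p = 0.396 with an estimated correlation. Of 6 WRKY genes 3 rose, with 3 also when adjusted over the list alone (camera adjusted p = 0.0134; adjusted p = 0.396 with an estimated correlation). Without Ossl replicate 2 the WRKY call ended (adjusted p = 0.0655). Here too the poly-A controls were lower on the Ossl arrays, by -1.19 at the 5' end and -0.54 at the 3' end (mean log2 against both other lines).

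In all, 4441 probe sets (11.2%) differed between Ossl and Osoc, 2351 higher and 2090 lower in Ossl, and 556 and 277 of these differed at least 2-fold. Without the variance trend 402 passed, among them those of BURP16, OsVIT1.2, JAZ2, DCL2A, PORA, CESA7 and CPS4, and not those of CYP99A2, NAS3 or PAL06. The number was 2571 without Osoc replicate 1 and 2342 without Osoc replicate 2. With all 6 arrays it was the largest of the 3 comparisons, but it was below that of Ossl against OsPE without Osoc replicate 1 (2751) or Osoc replicate 2 (2781), and at 3121 below that of Osoc against OsPE (3263) without Ossl replicate 2. In these fits the larger number came from lines with 2 arrays each, while the line left with 1 array lowered the precision of the other comparison, so they do not test the order.

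**Figure D3:**
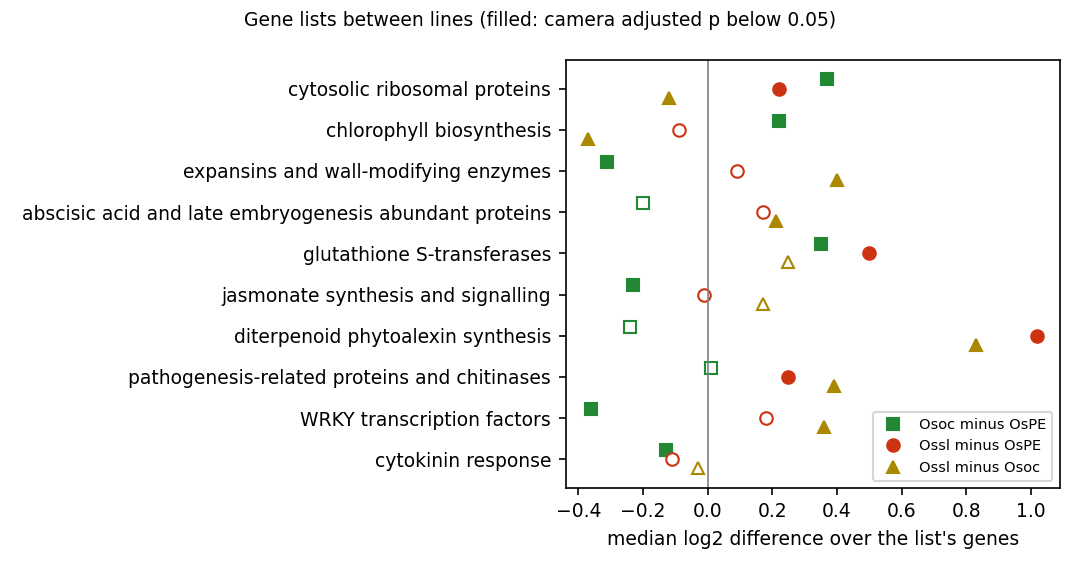
Median log2 difference between lines (horizontal axis) over the measured genes of each list with a call, with 1 symbol per comparison, filled where camera's adjusted p was below 0.05. Diterpenoid genes were highest in Ossl, at 1.02 against OsPE and 0.83 against Osoc, and no list passed with an estimated correlation.

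Of 81 list tests, 18 passed with camera's preset correlation. With an estimated correlation 0 passed with camera, where the smallest adjusted p was 0.204 and 12 had an unadjusted p below 0.05, and with fry 40 passed. The median and the mean differed in sign for the diterpenoid list in Osoc against OsPE, at -0.24 and 0.18 (log2; camera adjusted p = 0.854). Markers of grain tissue did not pass in any comparison, with camera adjusted p = 0.697 for Osoc against OsPE, 0.697 for Ossl against OsPE and 0.953 for Ossl against Osoc. For markers of root tissue the values were 0.697, 0.638 and 0.854.

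Probe sets that set 1 line apart from both others were 921 higher and 725 lower in Ossl, 668 higher and 721 lower in Osoc, and 402 higher and 435 lower in OsPE. BURP16, CPS4 and CM-LOX2 were highest in Ossl, and JAZ2, OsVIT1.2 and 1 probe set of QM1 lowest. In Osoc, DCL2A, NAS3, OsZIP3 and OsVIT1.2 were highest and BURP16 and CAD6 lowest, while in OsPE ITPK1 and JAZ10 were highest and ML, Pir7b and 1 of the 2 probe sets of OsPP2C45 lowest. OsSWEET15, the named gene that ranked highest in Osoc, lost its call against OsPE without OsPE replicate 2 (adjusted p = 0.0617), without Osoc replicate 1 (0.0747) and without Osoc replicate 2 (0.0878). In 20 simulations of unchanged arrays, with independent noise drawn from the fitted variance trend, the total had a mean of 0.05 and was at most 1. Independent lists of these sizes would share 459, but the 2 comparisons of a line share its arrays. Neither value is therefore a chance level for these data. The total in the data was 3872. It was 202 without the variance trend, 1909 and 1910 without OsPE replicate 1 and 2, and 2321 and 2176 without Osoc replicate 1 and 2.

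Among 64 reporter probe sets, RPTR-Os-K01193-1_at was among the brightest on every array, between percentiles 99.41 and 99.84. It read 17351 ± 1071 in OsPE, 22566 ± 244 in Osoc and 31207 ± 2353 in Ossl. Ossl was 1.8-fold higher than OsPE (adjusted p = 3.62e-06) and 1.38-fold higher than Osoc (adjusted p = 0.000436), and Osoc was 1.3-fold higher than OsPE (adjusted p = 0.00277). The last call ended without OsPE replicate 2 (adjusted p = 0.0651), and without the variance trend none of the 3 passed (adjusted p = 0.0664, 0.151 and 0.258). The other 63 read at most 111. Of these, RPTR-Os-U57609-2_s_at passed in Ossl against OsPE, at 7.9 ± 3.1 and 104 ± 9.3 (adjusted p = 0.0111). It did not pass without OsPE replicate 1 (0.12), OsPE replicate 2 (0.0907) or Ossl replicate 2 (0.0578), nor without the variance trend (0.0863).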

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

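The tests of added control RNA, of shorter labelled RNA, of other probe sets of a gene, of the nearest genes, of poorer labelling in all 33 probe sets and of 1 Ossl sample within a single list were chosen after the result was seen, as was the use of quantile normalization, itself planned, to test the authors' scaling.

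Poly-A control RNAs, which are added to each sample and were not used in the comparisons, read lower on the Ossl arrays, by a mean of -1.19 at the 5' end and -0.54 at the 3' end (log2 against the other lines, 4 controls). Less control RNA added to the Ossl samples, as the only cause, is argued against for dap. Its log2 ratio of the 3' to the 5' end was higher in Ossl by 1.29, beyond its within-line SD of 0.21. Less added RNA beside another cause stays open for dap, since its 3' end was lower as well, by -0.88. For thr the ratio was higher by 1.45, but its 5' probe set was near the floor in Ossl, at 29 ± 13.8, so less added RNA stays open. For lys and phe that ratio differed by -0.06, within its SD, with both ends lower, so less added RNA may account for them. Shorter labelled RNA in the Ossl samples as a whole stays open. Among rice control transcripts the ratio was highest in Ossl for both actin pairs, Gapdh and ubiquitin, but not for Cyph. Over the 5 pairs of rice control probe sets it was higher by 0.23 ± 0.11 (SE), and in 0 of them beyond both other lines by more than the SD. These pairs replaced a set with probe sets at the floor once values had been seen.

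Some probe sets were high in 1 line and near the floor in another. Of these, 33 differed at least 8-fold with the lower line below the 40th percentile on both arrays. By their IDs some share a target sequence, so the 33 are not independent readings. Loss of a segment holding several genes is argued against for the 11 with a gene. Their nearest genes, 22 in all, differed in the same direction by 0.03 (log2), the median over the 11, with an SE of the mean of 0.07. Exchange of a segment cannot be decided by this test, since exchanged genes need not differ in signal. A count of such genes near one another, planned earlier, gave 0 where random placing also gave a median of 0. A probe sequence that differs between the lines stays open, since a probe set of another target sequence followed in 1 of only 3 genes that have one (33.3%; exact 95% interval 0.8 to 90.6): LOC4335304, and not LOC4340325 or LOC4324944; an insertion or deletion in single genes was not tested. For LOC4324944, chosen like the others after its values were seen, 1 probe set read 16.8 ± 14.1, 12946 ± 69.5 and 8.6 ± 0.3 in OsPE, Osoc and Ossl, and the other 4305 ± 52.9, 7006 ± 425 and 5090 ± 301. Poorer labelling of the Ossl arrays is argued against as the source of all 33, since 23 had OsPE or Osoc as a lower line. An example is LOC4345101 with 17 ± 9.4, 10.3 ± 3 and 388 ± 79.5. The other 10 had Ossl alone as the lower line. Among these, LOC4324944, OsSWEET15 and some probe sets without a gene symbol were high in Osoc only. They read 16.8, 26.7, 23.3 and 36 in OsPE, against 12946, 192, 339 and 193 in Osoc. Poorer Ossl labelling cannot lower OsPE, so it is argued against for them. For those below both other lines it cannot be told apart. Of 9 such probe sets 6 were low in Ossl (66.7%, exact 95% interval 29.9 to 92.5). By their IDs some of these 6 share a target sequence. The interval takes each probe set as independent, so it is not reliable and nothing is concluded from it. The split of the probe sets by lower line was made after the values were seen.

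Diterpenoid and pathogenesis-related genes were higher in Ossl than in OsPE, by a median of 1.02 over 13 and 0.25 over 20 genes (log2). Of these 7 of 13 and 4 of 20 passed, and with camera's estimated correlation neither list did (adjusted p = 0.209 and 0.428). Of the 33, 19 had both Ossl arrays above both OsPE arrays, where exchangeable arrays would give 16.7%. Both lists had already been called higher in these same data, so this count adds no support. The share over all tested genes was not computed. A single Ossl sample as the source is argued against by the medians of both arrays over the 33 genes, 0.52 and 0.33, but stays open for the pathogenesis-related list, whose medians were 0.47 and 0.17, against 1.13 and 0.92 for the diterpenoid list. The authors' scaling is argued against by a median over the 33 genes of 0.46 after quantile normalization, against 0.45 before. The test of a compression of low signals decides nothing: the median was 0.38 over the 21 genes above the array median in all lines, but a compression shrinks differences and raises no line, so a value above 0, planned to count against it, does not. A difference between the lines may be the source, as a hypothesis, but a growth or handling batch stays open, since the sources name none and none was tested.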

How the results depend on the processing

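All alternatives were planned. None of the 257 named calls, each of 1 probe set in 1 comparison, and none of the 18 list calls reversed under those tried, and 52 named calls passed under every one. Without the variance trend the numbers passing were 431 over the 3 lines, 28 for Osoc against OsPE, 382 for Ossl against OsPE, 402 for Ossl against Osoc and 202 setting 1 line apart. Of the 257 named calls 202 were lost, as was 1 of the 18 list calls, and the cause was not tested. At adjusted p below 0.01 the numbers were 3065, 1398, 1598 and 2323, in the order of the first 4, and with at least 2-fold change 417, 761 and 833 for the 3 comparisons; both thresholds are stricter by construction. Leaving out 1 array gave 3740 to 5206 over the 3 lines, 1201 to 3278 for Osoc against OsPE, 1495 to 2781 for Ossl against OsPE, 2342 to 3787 for Ossl against Osoc, 1909 to 3351 setting 1 line apart and 17 to 21 lists, with fewer arrays in each fit and the lone array assumed to vary like the other lines. Of the lists, 0 passed with an estimated correlation and 40 with fry, which does not compare a list with other genes. The remaining alternatives stayed within 1.5 times: 4181 to 6431, 1980 to 3342, 2163 to 3583, 3329 to 4955, 2619 to 4523 and 17 to 20. Replicate numbers do not pair the samples. Signals below the 40th percentile, about 22.5 to 26, carry no reliable fold.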

Other observations

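The test of neighbouring genes in this part was chosen after the result was seen.

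NAAT1, a nicotianamine aminotransferase gene, read 1014 ± 53.7 in OsPE, 2783 ± 1.1 in Osoc and 1158 ± 21.1 in Ossl (SD, n = 2), and fell 2.39-fold from Osoc to Ossl (adjusted p = 9.89e-07). Of 41 heat shock genes 9 rose, 2 fell and 30 did not pass in Ossl against Osoc, and 9 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.605). HSF23 rose 2.69-fold, HSP24.1 2.28-fold and HSP81-1 1.58-fold.

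In Ossl against OsPE the gene DREB1B fell 2.55-fold, from 1256 ± 16.7 to 485 ± 57 (adjusted p = 8.6e-06), and the chlorophyll breakdown gene SGR rose 2.31-fold, from 705 ± 3.3 to 1667 ± 341 (adjusted p = 0.000105). SPY, a gibberellin signalling gene, fell 1.86-fold in Osoc against OsPE, from 2806 ± 26.8 to 1504 ± 50.9 (adjusted p = 2.61e-05). Both flavonoid genes measured, CHS and Cfi, fell in Osoc against OsPE, 1.44-fold and 1.28-fold.

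Genes changed at least 2-fold lay near one another in Ossl against OsPE, where 83 of 420 had another within 5 genes, against a median of 50 in 10000 random placements (permutation p = 4e-04, one-sided). For Ossl against Osoc the numbers were 77 of 447 and 56 (permutation p = 0.022), and for Osoc against OsPE 14 of 197 and 11 (permutation p = 0.334). Placements were drawn from all tested genes whatever their signal, in the gene order of the Japonica reference. These p-values therefore concern the placing of genes and not the difference between lines, and related neighbours with similar probe sequences were not set aside. CPS4, OsMAS and CYP99A2 lie close together in the annotation.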
